A study of Mus musculus with 4 samples.

How the data were processed

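Per the labels, total RNA was pooled from 4 mice for each genotype, 150 ng was labelled with Cy3 and each sample was hybridised to 1 one-colour Agilent mouse array. Per the file headers, spot intensity was read with Agilent Feature Extraction 10.7.1.1, which subtracted background, removed spatial and multiplicative trends and replaced very low values by small positive ones, and the deposited signal was not scaled between arrays. The flags for spots well above background, saturated or outlying are those of the same software per the file headers. All 4 arrays lay on 1 slide, so that position on the slide and genotype cannot be separated. Of the spots, 176, 138, 132 and 127 were outliers on control replicates 1 and 2 and Rbpj-deficient replicates 1 and 2 and were left out, and 0 were saturated. Columns of other samples left out numbered 0.

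The deposited table of normalised log2 values was made by the authors with steps not given in the sources used here. Set against the scanner signal it held log2 values scaled per array and centred on the median of each probe over the 4 samples, with Pearson r of 0.9997 to 0.9998 over 39485 probes, the same direction in all 4 columns, and column medians of 0.0532, -0.0305, -0.0340 and 0.0201. It served as an alternative only.

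Signal was taken to log2, each array was reduced by its 75th percentile over spots for genes, and spots of a probe were averaged. Probes well above background on both arrays of at least 1 genotype were kept, and each gene was represented by its probe with the highest mean. Genotypes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over the 17967 genes tested and a threshold of 0.05. SE values are those of the moderated fit, SD values are between the 2 arrays of a genotype, and the number of arrays limits the precision. The median log2 change over all genes tested was -0.01. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for reading, counting, permutations and drawing.

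Probes were named by matching the accessions in the array files to RefSeq annotation of GRCm38.p6, used only for names and for the order of genes, as the file headers give mm9 as the build of the array annotation. Of 39429 probes 26055 received 1 symbol, 0 received several and 13374 received none, so that 12749 of the genes tested had a symbol and the others were counted by probe target. Pydc3 was matched through a synonym to Ifi208, which does not adjoin Itgax.

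Gene lists were tested with camera at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 31 lists with at least 5 members tested. The list of Y chromosome genes and Xist had 3 members tested and was given as values. For each list, members past the threshold were counted over all genes and after Benjamini-Hochberg adjustment over the list alone. A gene well above background on both arrays of one genotype and neither of the other was given a lower bound of its fold, computed against the mean, over the arrays on which it was not measured, of its own signal or of the smallest log2 level well above background on that array, whichever was higher.

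The genes to be named were set by a rule: Rbpj, the 12 highest and the 12 lowest log2 changes among named genes past the threshold and well above background on all 4 arrays with no overlap of the genotypes, the 4 largest bounds in each direction, up to 2 highest and 2 lowest members past the threshold in each list or else the member farthest from 0, all tested Notch target genes and neighbours of Itgax and Rbpj, and the comparison genes Actb, Gapdh, Hprt, Tbp and B2m. Some results that the rule covers are not reported here. This rule, the lists and the alternatives were chosen before the data were examined. So were the tests, apart from those among the additional observations that are said there to be chosen after. S100a8, S100a9, Cd70, Ccl22, Cd40, Cd80, Cd86, Lpl, Fabp4, Pparg, Cd209a and, among the additional observations, the genes named outside this rule were chosen after their values were seen. Il4i1, Serpinb9, Mpo, Ngp, Trem2, Il1rn and Nt5e, members of lists that passed the threshold, also lie outside the rule and were named after their values were seen.

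The procedure was run on simulated arrays with the gene levels and the fitted variance prior of the comparison of Rbpj-deficient and control cells. Each of 5 runs held 200 changed genes among 17967. Genes were drawn independently with normal noise and no trend of the variance with signal, so the rates hold only where these assumptions do. It recovered 0.606% of genes changed by 0.5 on the log2 scale, 62.1% of those changed by 1 and 89.6% of those changed by 2, and 4.85% of its calls were false. Runs without changed genes gave 0 limma calls. Lists of 20 genes shifted by 0.5 passed in 5 of 5 runs, and unshifted lists passed at an unadjusted p in 1 of 5. Correlation between the members of a list was not simulated.

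Alternatives changed 1 choice at a time, except that the trended and robust prior set both together and normexp also replaced the processed by the median spot signal: normexp background correction (offset 50), quantile normalisation, median centring, the deposited table, no filter on dim probes, a filter on all 4 arrays, the mean of the probes of a gene, every probe tested, a trended and robust variance prior, saturated probes left out, a replicate block, a threshold of 0.01, limma's treat, camera with an estimated correlation or on ranks, fry, and each array left out in turn. The files used hold no mean spot signal, so normexp was run on the median signal in place of the mean that had been planned. Leaving out an array leaves a genotype with 1 array, which is then assumed to vary like the arrays of the other genotype. Camera with an estimated correlation rests on the spread left among the 4 arrays, so it could pass few lists here. The estimate was 0.82 for the cell cycle list, 0.45 for cholesterol synthesis, 0.23 for macrophage markers and 0.20 for maturation genes. It was 0.08 for neutrophil genes, 0.05 for lipid handling, 0.02 for Notch targets and -0.02 for oxidative phosphorylation. Where members correlate above the preset of 0.01, the preset gives p-values that are too small.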

Results

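RNA of bone marrow-derived dendritic cells with and without Rbpj was measured on 4 one-colour arrays. Marrow cells of C57BL/6 mice, 8 weeks old and labelled female, were grown for 6 days with 20 ng/mL GM-CSF, the cytokine that drives marrow precursors towards dendritic cells, and CD11c+ cells were then isolated. Control cells carried loxP-flanked Rbpj alleles alone. The Rbpj-deficient cells carried the same alleles and a cre recombinase expressed from the CD11c (Itgax) promoter. The comparison therefore joins the loss of Rbpj with the presence of the cre. As the series holds no array with the cre and an intact Rbpj, the effects of each cannot be told apart for any gene or list. Each genotype had 2 arrays, and the labels state that RNA was pooled from 4 mice per genotype. Nothing states that the 2 arrays of a genotype came from separate pools, so the p-values measure only the spread between these arrays, which may be technical. Of 43020 spots for genes on each array, 55.2% and 58.1% were well above background on the control arrays and 58.4% and 57.7% on the Rbpj-deficient arrays. The log2 levels of the 17967 genes tested correlated across genes at 0.997 within the control group and 0.998 within the Rbpj-deficient group, against 0.993 to 0.994 between the groups. The SD of the log2 difference between arrays was 0.25 and 0.23 within the groups and 0.36 to 0.38 between them. Levels are given as log2 signal relative to the 75th percentile of the array, and precision is limited by the number of arrays.

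Rbpj, the DNA-binding protein through which Notch receptors act on their target genes, was lower on both Rbpj-deficient arrays. Its brighter probe read 2.69 and 2.61 on the control arrays and 1.37 and 1.44 on the Rbpj-deficient arrays, a log2 change of -1.25 (SE 0.06, limma adjusted p = 0.0278), which left 42.1% of the control signal. The dimmer probe fell to 42.3%. The position of these probes relative to the floxed exons is not known here, so the remaining signal does not measure how many cells had lost the gene. The call was lost when any 1 array was left out, with log2 changes between -1.21 and -1.29. An arm of 1 array then took its spread from the other arm, and fewer arrays were left to estimate that spread. Itgax, whose promoter drives the cre, read 6.66 in control and 6.55 in Rbpj-deficient cells, a log2 difference of -0.11 (adjusted p = 0.523).

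The Rbpj-deficient cells expressed more of the chemokine Ccl24 (eotaxin-2), the lymphoid surface protein Cd7, the ephrin receptor Epha2 and the dendritic cell lectin Clec4a4, and less of Aldh1a2, which makes retinoic acid, of the annexin Anxa8, of fibronectin (Fn1) and of the IL-33 receptor Il1rl1. Ccl24 rose by 3.08 on the log2 scale, or 8.44-fold (SE 0.17, adjusted p = 0.0289), from a level of -5.38 ± 0.33 to -2.30 ± 0.02 (SD, n = 2). Cd7 rose by 2.88, or 7.35-fold (SE 0.11, adjusted p = 0.0165). Aldh1a2 fell by 2.31 (SE 0.13, adjusted p = 0.0302) from 1.69 ± 0.21 to -0.62 ± 0.13. Anxa8 fell by 2.30 (SE 0.08, adjusted p = 0.0165) on the brighter of its 2 probes, and the other stood at -1.20. Epha2 rose by 2.14 and Clec4a4 by 2.02. The other 8 of the 12 named genes with the highest changes were the organic anion transporter Slco4a1 (1.80), the Ras regulator Dab2ip (1.74), the transcription factor Klf5 (1.73), the netrin receptor Unc5b (1.68), the Src-like adaptor Sla2 (1.65), the myosin light chain Myl10 (1.65), the transcription factor Gata3 (1.61) and the zinc finger gene Zfp799 (1.59). The other 10 of the 12 lowest were Upb1, an enzyme of pyrimidine breakdown (-1.97), Cpne6 (-1.79), the transcriptional repressor Gfi1b (-1.57), Fn1 (-1.56), Dmrta2 (-1.54), Ms4a8a (-1.46), Il1rl1 (-1.43), the haem-binding Hebp2 (-1.37), Dscaml1 (-1.34) and Trnp1 (-1.34). The 3 probes of Il1rl1 ranged from -1.43 to -0.62 and the 2 of Trnp1 from -1.34 to -0.81. Sizes of dim genes depended on the background handling. Normexp adds an offset of 50 to every signal and so shrinks dim changes. With it Ccl24 stood at 1.74, below Cd7 at 2.80, Epha2 at 1.12, Klf5 at 0.83, Unc5b at 0.86, Zfp799 at 0.89, Sla2 at 1.09, Upb1 at -0.93, Cpne6 at -1.05 and Dscaml1 at -0.88. Of the 60 named genes that passed, all 60 passed with normexp too, and the log2 change of 22 was more than 1.5 times smaller.

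In all, 338 of the 17967 genes passed the threshold of 0.05 in limma with Benjamini-Hochberg adjustment, 187 higher and 151 lower in Rbpj-deficient cells, and 121 of them changed at least 2-fold, 72 up and 49 down. Of the 338, 249 had a gene symbol, 120 higher and 129 lower. Groups did not overlap for 59.1% of the genes tested, where chance gives 33.3%, and 4329 genes had an unadjusted p under 0.05. The calls rest on small margins, since the smallest adjusted p was 0.0135. Without control replicate 1 limma called 119 genes, 14 higher and 105 lower (16 of them among the 338), without control replicate 2 136, 32 higher and 104 lower (32 shared). Without Rbpj-deficient replicate 1 or replicate 2 limma called 0, with 3589 and 2960 genes at an unadjusted p under 0.05. A variance prior that both followed the signal level and was made robust to outlying genes called 1548 genes, of which 44.8% were higher, against 55.3% of the 338.

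**Figure D1:**
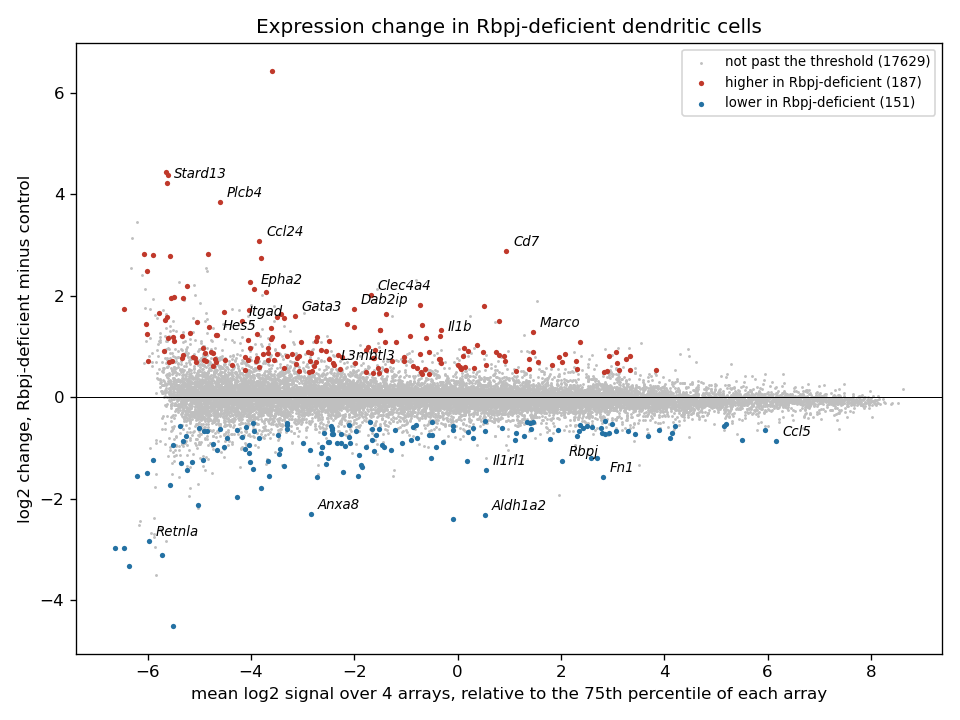
Change of each of the 17967 genes tested (y axis, log2, Rbpj-deficient minus control) against its mean log2 signal over 4 arrays relative to the 75th percentile of the array (x axis). Red points are the 187 genes higher and blue points the 151 genes lower in Rbpj-deficient cells, and Ccl24 at 3.08 and Aldh1a2 at -2.31 stand among the named genes with large changes.

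Some Notch-linked genes rose. Hes5, a classical target of Notch signalling, rose by 1.23 on the log2 scale (SE 0.09, adjusted p = 0.0333), with 1 of 2 control arrays well above background and a change of 0.50 with normexp, and Gata3, a target in lymphocytes, rose by 1.61 (adjusted p = 0.0289). Of 20 Notch target genes on the array 11 entered the test, and Hes1, Hey1, Nrarp and Dtx1 were among those that did not. Hes5 and Esam entered through the Rbpj-deficient arrays alone. Of the 11 tested, Hes5 and Gata3 rose, none fell and 9 did not pass. Adjusted over the list alone 6 were higher and 1, Nfkb2 (-0.33), was lower. Myc (0.32), Tcf7 (0.35, and 0.15 with normexp) and Ccnd1 (0.41) lay above 0 without passing over all genes, as did Esam (1.65, adjusted p = 0.105). Esam was not well above background in control cells and at least 1.79-fold brighter in Rbpj-deficient cells on the processed signal, with a log2 change of 0.32 with normexp. Bcl2 (0.14), Gata2 (0.15), Il2ra (-0.08) and Cdkn1a (-0.12) differed little. The tested members shifted up as a list in camera (median 0.32, adjusted p = 0.0123), but not with an estimated correlation (adjusted p = 0.636), which could pass few lists. The shift was also lost on ranks (adjusted p = 0.0525) and with a filter on all 4 arrays (median 0.15, adjusted p = 0.107). Without Rbpj-deficient replicate 2 the median of the list was 0.27, and the list did not pass there either. With dim genes included its median was -0.07 (adjusted p = 0.0681). Among 35 receptors, ligands and cofactors of the pathway, the coactivator Maml3 (0.72, adjusted p = 0.0379) and L3mbtl3 (0.64, adjusted p = 0.0393), known to bind RBPJ as a corepressor, rose, and none fell. The 3 probes of Maml3 ranged from 0.29 to 0.72. Adjusted over the list alone 7 were higher and 1 lower, and the list did not shift (median 0.06, adjusted p = 0.168).

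Some genes that mark the mature state of dendritic cells fell in Rbpj-deficient cells, while most did not pass. The chemokine Ccl5 fell by 0.85 (SE 0.05, adjusted p = 0.0322), from 6.59 ± 0.01 to 5.74 ± 0.02, or 1.80-fold, and Nudt17 by 0.69 (adjusted p = 0.0372), Il4i1 by 0.64 (adjusted p = 0.0379) and Serpinb9 by 0.47 (adjusted p = 0.0465). Of 33 maturation genes tested these 4 fell, none rose and 29 did not pass, and 28 of the 33 lay below 0. Adjusted over the list alone 18 were lower and none higher, among them Cd70 (-0.91), the chemokine Ccl22 (-0.78) and the migration receptor Ccr7 (-0.48), while the costimulatory genes Cd80 (-0.15), Cd86 (0.17) and Cd40 (0.09) were not. The list shifted down in camera (median -0.32, adjusted p = 6.98e-08), with adjusted p = 0.636 with an estimated correlation and 0.0526 in fry. The estimated correlation between its members was 0.20, against the preset of 0.01.

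Lipid genes lay mostly lower. Of 24 genes of cholesterol synthesis none passed over all genes, 23 lay below 0 and 5 were lower adjusted over the list alone, led by Insig1 (-0.47, adjusted p = 0.0556). That list shifted down (median -0.25, adjusted p = 1.52e-06, and adjusted p = 0.636 with an estimated correlation and 0.114 in fry). The estimated correlation between its members was 0.45, against the preset of 0.01. Its median was -0.17 without Rbpj-deficient replicate 1 and -0.33 without Rbpj-deficient replicate 2. Of 25 lipid handling genes governed by LXR and PPAR-gamma only Angptl4, an inhibitor of lipoprotein lipase, passed, and it rose by 0.83 (adjusted p = 0.0322). Adjusted over the list alone 9 were lower and 1 higher, with lipoprotein lipase Lpl at -0.71, the fatty acid-binding Fabp4 at -0.69, the scavenger receptor Cd36 at -0.70 and Pparg at -0.57. The median was -0.24 and the shift passed (adjusted p = 0.0123, and adjusted p = 0.636 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.0542) or in fry (adjusted p = 0.0743). Of 33 subunits of oxidative phosphorylation 32 lay below 0 by small amounts (median -0.10), the lowest being Atp5o at -0.18 (adjusted p = 0.159), and none passed, over all genes or adjusted over the list alone. The list shifted down (adjusted p = 0.00267, and adjusted p = 0.636 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.0518) or under quantile normalisation (adjusted p = 0.223).

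Some markers of other cells changed, and most did not pass. Of 20 neutrophil and granule genes 4 rose, the stefins Stfa2l1 (0.90, adjusted p = 0.0445) and Stfa2 (0.81, adjusted p = 0.0379), myeloperoxidase Mpo (0.74, adjusted p = 0.0378) and Ngp (0.54, adjusted p = 0.0445), none fell and 16 did not pass. Adjusted over the list alone 14 were higher and none lower, among them S100a8 (0.83) and S100a9 (0.85). The list had the highest median of those tested (0.61, camera adjusted p = 1.44e-06, and adjusted p = 0.636 with an estimated correlation). Of 28 monocyte and macrophage markers the scavenger receptor Marco rose by 1.29 (adjusted p = 0.0322), and Fn1, the Fc receptor Fcgr1 (-0.61, adjusted p = 0.0424) and Trem2 (-0.53, adjusted p = 0.0445) fell. The other 24 did not pass, and adjusted over the list alone 3 were higher and 7 lower. That list shifted down (median -0.15, adjusted p = 0.0351, and adjusted p = 0.668 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.395) or Rbpj-deficient replicate 2 (adjusted p = 0.0983), nor under quantile (adjusted p = 0.0705) or median scaling (adjusted p = 0.0597), with dim genes included (adjusted p = 0.0617) or in fry (adjusted p = 0.199). Among 13 mast cell, basophil and eosinophil markers the histamine-forming enzyme Hdc rose (0.48, adjusted p = 0.0477) and Il1rl1 and Siglecf (-0.63, adjusted p = 0.0379) fell, with no shift of the list (adjusted p = 0.682) and 4 higher and 3 lower adjusted over the list alone. Of 13 T, B and natural killer cell markers only Klrb1c passed, and it rose by 1.14 (adjusted p = 0.0379), or 0.60 with normexp. That list did not pass (median 0.39, and 0.21 to 0.72 without 1 array, adjusted p = 0.166) but did without Rbpj-deficient replicate 1 (adjusted p = 0.0221), and 4 members were higher and 2 lower adjusted over the list alone.

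Dendritic cell subset markers did not move together. Of 20 cDC2 markers only Clec4a4 rose, and Cd209a, a lectin of the same cells, stood at -1.33 (SE 0.39, adjusted p = 0.159). The median was -0.21 and the mean 0.06 (adjusted p = 0.434, direction down), with 4 higher and 8 lower adjusted over the list alone. Of 14 plasmacytoid dendritic cell markers Cd7 rose and the receptor Klra17 (-1.24, adjusted p = 0.0322, and -0.74 with normexp) and the adaptor Blnk (-1.19, adjusted p = 0.0322) fell, with a median of -0.11, a mean of 0.11 and no shift (adjusted p = 0.726, direction down). Adjusted over the list alone 4 were higher and 5 lower. None of 14 shared dendritic cell markers passed (median -0.13, list adjusted p = 0.166; 1 higher and 6 lower adjusted over the list alone), and none of 12 cDC1 markers, where Cd36 was the farthest from 0 (adjusted p = 0.0502, list adjusted p = 0.459; 2 lower adjusted over the list alone). Of 10 erythroid and megakaryocyte markers none passed, with Itga2b at 0.82 (adjusted p = 0.0909, and 0.33 with normexp). That list did not pass either (adjusted p = 0.363), with 2 higher adjusted over the list alone. Of 9 stromal and endothelial markers none passed, with Sparc at -0.60 (adjusted p = 0.622, and 0.23 without Rbpj-deficient replicate 1), a median of -0.08, a mean of 0.01 and a test pointing up (adjusted p = 0.682; 1 higher adjusted over the list alone).

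**Figure D2:**
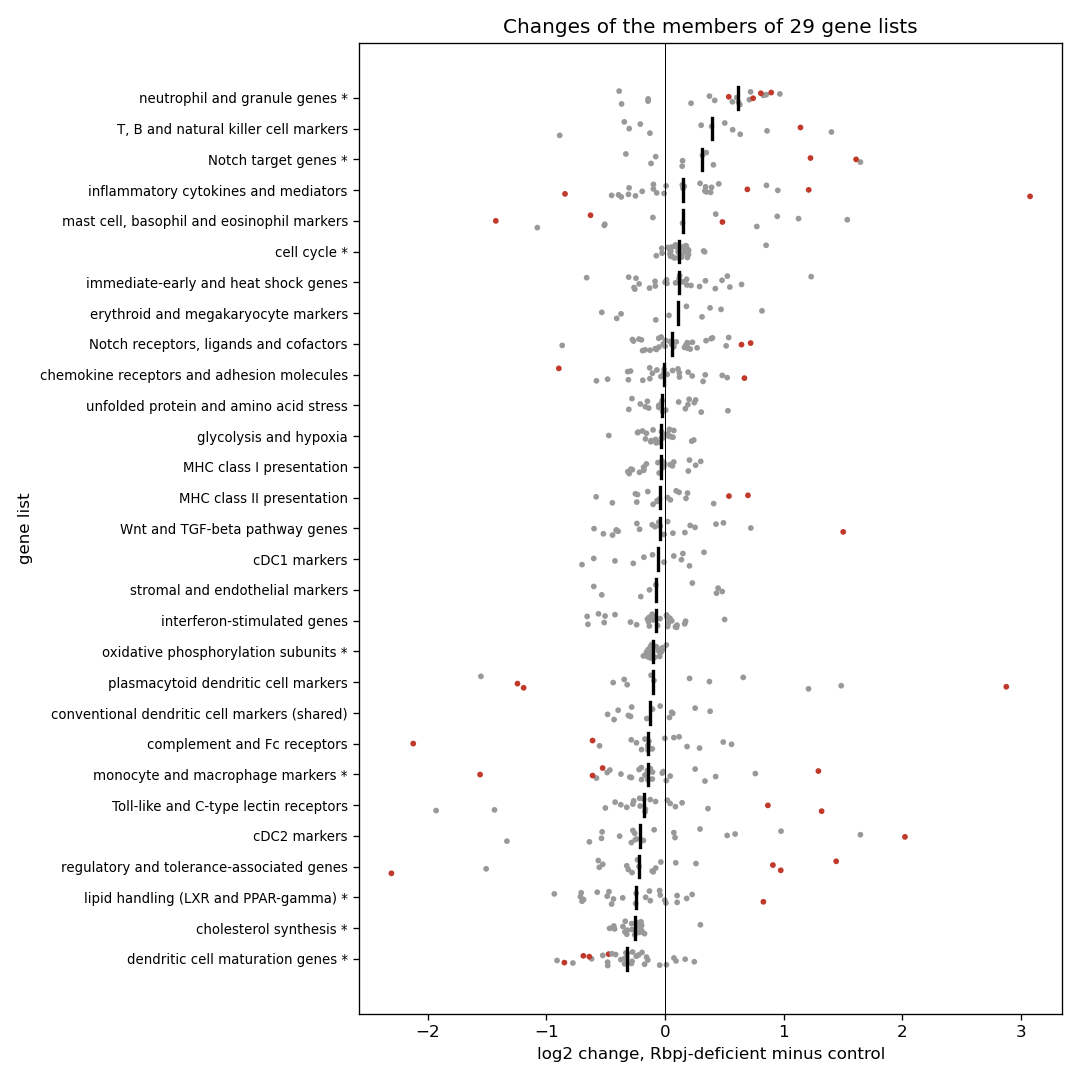
Log2 change (x axis, Rbpj-deficient minus control) of the tested members of 29 gene lists (y axis). Each point is a gene, red where it passed the threshold over all genes, the black bar is the median of the list, and an asterisk marks the 8 lists that passed in camera with a preset correlation, from the neutrophil list at a median of 0.61 to the maturation list at -0.32.

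Inflammatory, regulatory and receptor genes went both ways. Il1b, the precursor of interleukin-1 beta, rose by 1.21 (SE 0.11, adjusted p = 0.0379) and its receptor antagonist Il1rn by 0.69 (adjusted p = 0.0379), whereas the chemokine Ccl9 fell by 0.84 (adjusted p = 0.0379). With Ccl24, 3 of 28 inflammatory genes rose and 1 fell, 8 were higher and 6 lower adjusted over the list alone, and the list did not shift (median 0.15, and 0.02 to 0.23 without 1 array, adjusted p = 0.214). Of 19 regulatory genes Tgfb3 (1.44, adjusted p = 0.0379), the receptor Havcr2, known as TIM-3 (0.98, adjusted p = 0.0324), and Nt5e, which forms adenosine, rose, and Aldh1a2 fell. Their median was -0.22 (adjusted p = 0.214), with 4 higher and 7 lower adjusted over the list alone. Of 22 Toll-like and C-type lectin receptors langerin, Cd207 (1.32, adjusted p = 0.0379), and Clec5a (0.87, adjusted p = 0.0379, and 0.34 with normexp) rose and none fell. The list lay lower without passing (median -0.17, adjusted p = 0.105; 2 higher and 6 lower adjusted over the list alone) and passed without Rbpj-deficient replicate 2 (adjusted p = 0.0123). E-cadherin, Cdh1 (0.67, adjusted p = 0.0379), rose among 26 chemokine receptors and adhesion molecules, of which 1 rose and 1 fell (list adjusted p = 0.949; 4 higher and 6 lower adjusted over the list alone). Of 19 complement and Fc receptor genes 2 fell, among them Fcgr1, and none rose (median -0.14, and -0.18 to -0.05 without 1 array, list adjusted p = 0.166; 3 lower adjusted over the list alone).

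Antigen presentation changed at H2-Oa (0.54, adjusted p = 0.0447) and H2-Ob (0.70, adjusted p = 0.0379), the chains of a molecule that holds back class II peptide loading, which rose among 19 class II genes. The median of that list was -0.05, its mean 0.01 and its test pointed up (adjusted p = 0.949; 3 higher and 3 lower adjusted over the list alone). None of 22 class I genes passed, over all genes or adjusted over the list alone (Cybb -0.31, adjusted p = 0.117; list adjusted p = 0.630). The transcriptional regulator Id1 rose 2.83-fold (adjusted p = 0.0322) among 22 Wnt and TGF-beta genes, with a median of -0.05, a mean of 0.02 and a test pointing down (adjusted p = 0.949; 5 higher and 5 lower adjusted over the list alone).

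Some lists of general cell state moved with single arrays. Of 32 cell cycle genes none passed, over all genes or adjusted over the list alone, and Tyms was the farthest from 0 (0.85, SE 0.49, adjusted p = 0.360), at 0.17 without Rbpj-deficient replicate 1 and 1.53 without Rbpj-deficient replicate 2. The list passed as shifted up (median 0.12, adjusted p = 0.0425, and adjusted p = 0.841 with an estimated correlation), but not without control replicate 1 (adjusted p = 0.0860) or replicate 2 (adjusted p = 0.116), with the mean of a gene's probes (adjusted p = 0.0503) or in fry (adjusted p = 0.658). Its median turned to -0.06 without Rbpj-deficient replicate 2 (adjusted p = 0.249) and was 0.33 without Rbpj-deficient replicate 1 (adjusted p = 3.64e-09). None of 32 interferon-stimulated genes passed (Rsad2 -0.66, adjusted p = 0.187; list adjusted p = 0.556), yet that list shifted down without Rbpj-deficient replicate 2 (adjusted p = 0.000199), as did 25 glycolysis and hypoxia genes (P4ha1 -0.47, adjusted p = 0.0908; list adjusted p = 0.459) without control replicate 1 (adjusted p = 0.000976). Neither list had a member past the threshold adjusted over the list alone. Of 27 immediate-early and heat shock genes none passed (Nr4a1 1.23, SE 0.34, adjusted p = 0.146; list adjusted p = 0.166), and 7 were higher and 5 lower adjusted over the list alone. Of 21 genes of the unfolded protein and amino acid stress responses none passed, over all genes or adjusted over the list alone. Chac1 stood at 0.53 (adjusted p = 0.187), and at 0.29 to 0.77 without 1 array. That list had a median of -0.02, a mean of 0.03 and a test pointing up (adjusted p = 0.955). Besides those named without 1 array, lists outside the 8 that passed in some alternative were the Notch receptors and cofactors and the shared dendritic cell markers in fry (adjusted p = 0.0258 for both) and the Itgax neighbours in fry (adjusted p = 0.0372). Others were the T, B and natural killer cell markers with median centring (adjusted p = 0.0407), the immediate-early genes with dim genes included (adjusted p = 0.0412), and the Toll-like and C-type lectin receptors and the Rbpj neighbours with normexp (adjusted p = 0.0433 for both). In all, 8 of 31 lists tested passed with the preset correlation of camera, 3 up and 5 down, and 0 with an estimated one, while 7 passed on ranks and 6 in fry. Of the 8, only the Notch target, neutrophil and oxidative phosphorylation lists passed in fry. Comparison genes did not pass, with Actb at -0.11, Gapdh at -0.08, Hprt at -0.03 (0.02 under quantile normalisation), Tbp at 0.11 and B2m at -0.30 (adjusted p = 0.160).

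**Figure D3:**
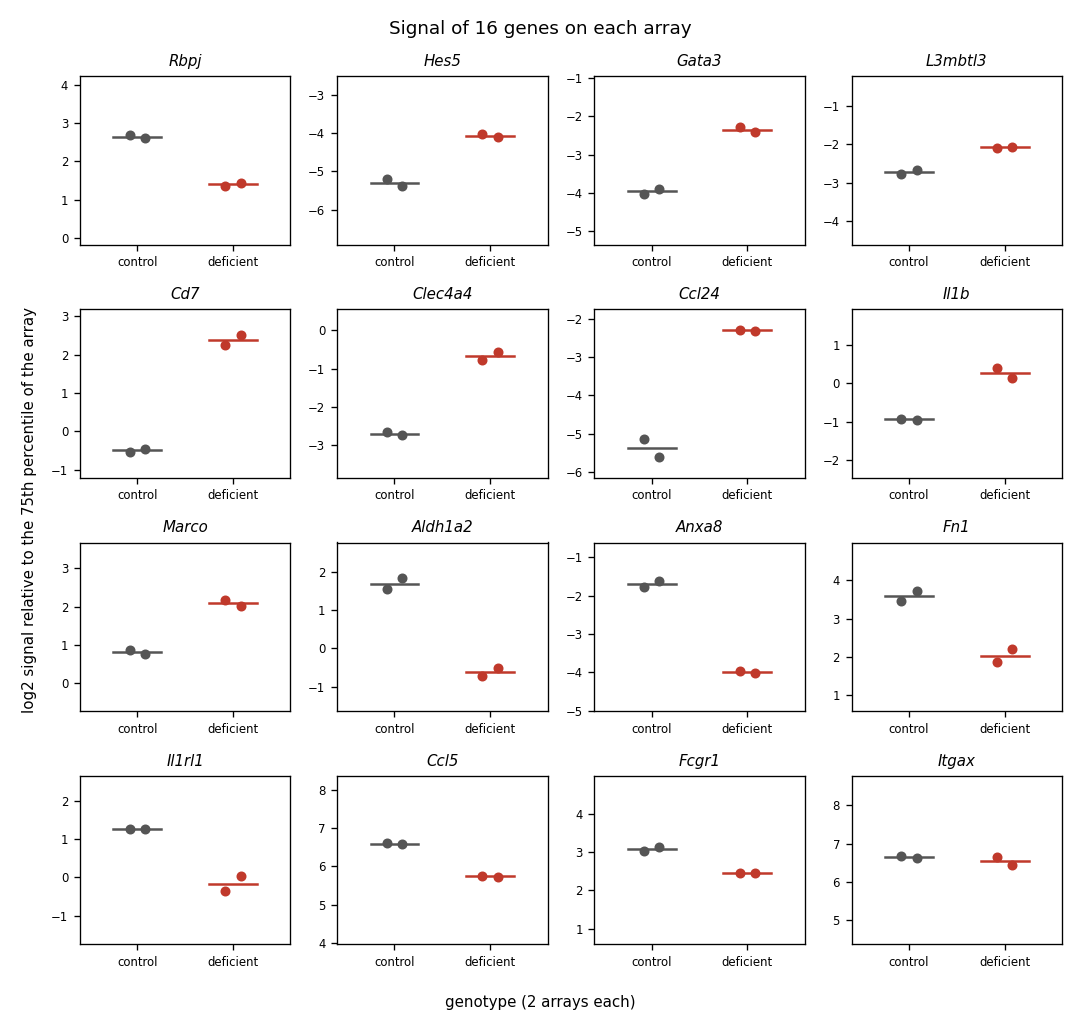
Log2 signal of 16 genes on each array, relative to the 75th percentile of the array (y axis, spanning the same length in each panel), by genotype (x axis). Points are the 2 arrays of a genotype and bars their mean, and the arrays of Rbpj lie at 2.69 and 2.61 in control against 1.37 and 1.44 in Rbpj-deficient cells, while those of Itgax overlap.

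Some genes were measured in only one genotype. The phospholipases Plcb4 and Plcb1, which neighbour each other, were well above background on both Rbpj-deficient arrays and neither control array, at least 7.94-fold (adjusted p = 0.0322) and at least 2.79-fold brighter (adjusted p = 0.0322). Stard13 (at least 4.44-fold, adjusted p = 0.0445) and Wfdc9 (at least 2.88-fold, adjusted p = 0.0353) followed. In the other direction the olfactory receptor Olfr356 (at least 3.21-fold, adjusted p = 0.0135), Plekhg1 (at least 2.52-fold, adjusted p = 0.0289) and Retnla, a gene of alternatively activated macrophages (at least 2.47-fold, adjusted p = 0.0379), were measured on both control arrays and neither Rbpj-deficient array. These bounds hold for the processed signal alone. With the offset of normexp the folds were 4.19 for Plcb4, 1.75 for Plcb1, 2.69 for Stard13, 1.62 for Wfdc9, 1.83 for Olfr356, 1.36 for Plekhg1 and 1.63 for Retnla. Over all probes 229 were well above background only in Rbpj-deficient cells and 84 only in control cells, and 49 genes of this kind passed the threshold, 32 and 17. When 1 array was left out these probe counts lay between 282 and 843 and between 117 and 597, as a single array then decided a group. Their order turned without control replicate 1, with 282 only in Rbpj-deficient and 597 only in control cells, against 843 and 308 without control replicate 2, 692 and 170 without Rbpj-deficient replicate 1 and 767 and 117 without Rbpj-deficient replicate 2.

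Genes next to the manipulated loci were examined for changes. Itgad, which adjoins Itgax in the mouse gene order, rose by 1.51 (SE 0.06, adjusted p = 0.0165), or 0.68 with normexp, with 1 of 2 control arrays well above background, and the following gene Cox6a2 stood at 1.49 (SE 0.35, adjusted p = 0.116), or 0.99 without Rbpj-deficient replicate 1 and 1.98 without Rbpj-deficient replicate 2. On the other side Itgam (0.07), Pycard (-0.11) and Prss8 (-0.25) did not pass, nor did Armc5 (0.02) and Rusf1 (0.08), and the list did not shift (median 0.05, adjusted p = 0.363; 1 higher adjusted over the list alone). That list of 10 tested genes also held Ifi208 (-0.02), reached through an older synonym, which is not a neighbour. Of 9 genes at the Rbpj locus only Rbpj itself fell. Sepsecs (-0.59, adjusted p = 0.192), Zcchc4 (-0.27), Pi4k2b (-0.21), Smim20 (-0.15), Anapc4 (-0.10), Tbc1d19 (-0.03), Dhx15 (0.03) and Stim2 (0.30) did not pass. Without 1 array Sepsecs lay between -0.87 and -0.32 and Pi4k2b between -0.34 and -0.09. The list did not shift (median -0.15, adjusted p = 0.0995), with 2 lower adjusted over the list alone. Without any 1 array, between 45 and 60 of the 60 named genes that passed lost their adjusted call while none changed direction.

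No sex-linked gene of the list passed. Of 6 Y-linked genes 3 were well above background on all 4 arrays, namely Ddx3y (0.00), Eif2s3y (-0.07) and Uty (-0.17). Both probes for Xist, the RNA of the inactive X chromosome of female cells, stayed below that mark on all 4 arrays, although the labels give the mice as female.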

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

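The alternatives were chosen before the data were examined, except that normexp was planned on the mean spot signal and run on the median. The number of genes past the threshold, 338, stayed within 1.5 times under quantile normalisation (316), median centring (439), the deposited table (348), a filter on all 4 arrays (470), the mean of a gene's probes (325) and every probe tested (361). Leaving out saturated probes could not change it (338), as 0 spots were saturated. The number rose to 896 with normexp on median signal, where 59 changed at least 2-fold, and to 1548 with the trended and robust prior. With no filter on dim probes, limma called 0 genes and 0 at 2-fold (3654 at an unadjusted p under 0.05), with 32494 genes tested. The replicate block, which treats equal replicate numbers as paired, gave 0 and 0 (3677 at an unadjusted p under 0.05), although the numbers pair nothing visible: the differences between replicates of the genotypes correlated at -0.0472. A threshold of 0.01 gave 0 and 0 (4329 at an unadjusted p under 0.05). Treat against a log2 change of 1 left 5 genes. Leaving out 1 array gave 0 to 136 genes, and 0 to 136 at 2-fold, with 1 array in a genotype: 119 without control replicate 1, 136 without control replicate 2 and 0 without either Rbpj-deficient replicate (limma, 3589 and 2960 at an unadjusted p under 0.05). The number of lists past the threshold, 8, was 5 to 9 without 1 array and 0 with an estimated correlation in camera, against 7 on ranks and 6 in fry. Of the 8 lists, only the Notch target, neutrophil and oxidative phosphorylation lists passed in fry, and the rest of the 6 lay outside the 8. The SD of the log2 difference between replicates was 0.162 in control cells with normexp, and 0.544 and 0.540 in control and Rbpj-deficient cells with no filter, as dim probes then count. Rbpj lost its call with no filter (adjusted p = 0.260), with the replicate block (adjusted p = 0.101) and at a threshold of 0.01 (adjusted p = 0.0278). Its log2 change of -1.25 could not move in these settings. Without 1 array it lay between -1.29 and -1.21. The median of the cell cycle list reversed to -0.0629 without Rbpj-deficient replicate 2 (adjusted p = 0.249) and was 0.33 without Rbpj-deficient replicate 1. For the 106 named genes, 1264 of 1685 values under alternatives kept their side of the threshold, 405 lost the call and 16 gained one. The sign changed in 19 of these values, in 11 genes that had not passed, and in 0 of the 60 genes that had. Where no construction is named, the cause was not tested. Signal over background limits the genes below the detection floor.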

Other observations

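The tests of chance placement, of pairs sharing 3 letters and of noise at Itgad were set before their results were seen, and all other tests in this part, with the genes named here, were chosen after. Some genes better known from lymphocytes were among the changes, although the list of T, B and natural killer cell markers did not pass (adjusted p = 0.166) and no list was made of these genes. The tyrosine kinase Txk was measured only in Rbpj-deficient cells, at least 1.99-fold brighter (adjusted p = 0.0165), and Cd7, Gata3, Sla2 and Klrb1c rose, whereas Blk (2.49, adjusted p = 0.0657) and Lck (0.30, adjusted p = 0.244) did not pass. The actin regulator Avil rose by 2.28 (adjusted p = 0.0165), with 1 of 2 control arrays above background, and the prostacyclin synthase Ptgis stood at 1.89 (adjusted p = 0.0588). Probe A_55_P2173333, which has no gene symbol here, was measured only in Rbpj-deficient cells, at least 39.0-fold brighter (adjusted p = 0.0165).

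C-type lectins of the Cd209 family lay lower in Rbpj-deficient cells without passing, at -1.93 for Cd209d (adjusted p = 0.105), -1.44 for Cd209e (adjusted p = 0.0766), -1.33 for Cd209a (adjusted p = 0.159) and -0.22 for Cd209c (adjusted p = 0.585). Of 111 olfactory and vomeronasal receptor genes tested limma called 3, against 338 of 17967 genes in all, and 48 of the 111 lay above 0 and 63 below. Olfr373, on in all arrays, did not pass (-0.25, adjusted p = 0.153). The 3 called were lower and entered the test through the control arrays alone. Olfr1158 (at least 1.63-fold, adjusted p = 0.0165), Vmn2r76 (at least 2.22-fold, adjusted p = 0.0165) and Olfr356 were measured only in control cells. The X-linked genes Slx (2.02, adjusted p = 0.136) and Xlr (1.81, adjusted p = 0.145) were higher without passing.

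Some neighbouring genes differed the same way. Of 12749 named genes placed in order, 12 neighbouring pairs differed at least 2-fold in the same direction, among them Plcb1 and Plcb4, the 1 pair with both members past the threshold, while 3 pairs, such as Itgad and Cox6a2, had 1 such member and 8 had none. Shuffling the changes gave a mean of 1.46 pairs and at most 7. The share was 0.001, the smallest that 1000 shuffles can give, which argues against chance placement of the 12 as a set. Relatives so named did not make the whole excess, and whether their own pairs arose from probes reading one another was not tested. Leaving out such pairs, with the same first 3 letters, left 7 pairs and again a share of 0.001. Of those 7, 4 were X-linked Slx, Xlr or provisional gene models, and a rule made from these pairs left 3 pairs and a share of 0.141, so relatives under other symbols reading one another stay open, as does chance for the 3 pairs left, Itgad and Cox6a2 among them. Of genes of like brightness 0.890% moved as far as Itgad, whose change was 0.68 with normexp. As Itgad was the 1 of 10 tested genes in the list of Itgax neighbours that passed, this share cannot exclude noise of dim probes. Genes carried with the cre transgene could explain Itgad and Cox6a2 (0.99 to 1.98 without 1 array). That cannot be told apart from an effect of Rbpj loss, as 0 arrays with the cre and an intact Rbpj exist in the series.

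Y-linked signal was present in arrays labelled female. Ddx3y read 0.93 in control and 0.94 in Rbpj-deficient cells and Eif2s3y 1.65 and 1.58, and 3 of 6 Y-linked genes were well above background on all 4 arrays, whereas 0 of 8 readings of the 2 Xist probes were, which argues against female cells only unless both probes fail. Y probes reading X-linked relatives could give the 3 genes and cannot be told apart from male cells without a female array. The pattern was alike in both genotypes, and no biological explanation was tested.

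Neutrophil granule genes were higher as a list and macrophage genes lower with the preset correlation of camera, and neither with an estimated one (adjusted p = 0.636 and 0.668), and the macrophage shift was also lost without control replicate 2 (adjusted p = 0.395). A lower share of dendritic cells in the isolate was not decided by these lists. If both kinds of other cells took their place, both lists would rise. Without 1 array the neutrophil median was 0.51 to 0.70 and the macrophage median -0.20 to -0.10. More neutrophil-lineage cells alone need not raise the macrophage list. The permutation of members (means 0.47 and -0.13 over 20 and 28 members, p = 2e-05) adds nothing, as these lists were picked for moving apart. The same holds for the medians. Near-identical stefin probes did not carry the neutrophil shift, as the median without stefins was 0.55 over 16 members. More neutrophil-lineage cells in the isolate and regulation of these genes within dendritic cells cannot be told apart, since both would raise the list above random lists matched on expression, which reached that median in a share of 0.0001, the smallest that 10000 lists can give. The neutrophil list was picked after its median was seen, and random members were drawn independently of one another, so the share adds nothing. S100a8 read 2.58 in control and 3.41 in Rbpj-deficient cells and S100a9 3.89 and 4.74, neither past the threshold. Of the 20 members 16 lay above 0, among them Mpo (0.74), Ctsg (0.62), Ms4a3 (0.61) and Prtn3 (0.37). The 4 below 0 included Elane (-0.14). The CD11c+ isolation would be expected to remove neutrophils, but their share in the isolate is not known here.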
